A study of Homo sapiens with 4 samples.

How the data were processed

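Gene expression in KGN cells, a human granulosa tumour line, was measured on 4 Affymetrix HG-U133 Plus 2.0 arrays, 1 for each combination of control or YAP/TAZ siRNA with and without 8Br-cAMP. Per the labels' protocols, cells were transfected with control siRNA (10 nM) or with YAP and TAZ siRNAs (5 nM each), the medium was changed 48 h later, and 8Br-cAMP (0.5 mM) was given for 24 h. Total RNA was amplified and biotin-labelled as cRNA with a 3' in vitro transcription kit, per the labels' protocols, so that signal comes mainly from the 3' end of transcripts.

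The deposited values are probe set intensity values on a linear scale. Per the submitters' processing notes they were made by RMA in Affymetrix Expression Console, with versions not given in the sources used here. The values themselves do not look like RMA output, which is on a log scale and has one distribution for every array. They ran down to 0.081, differed in distribution between arrays, and had a 2% trimmed mean of 500.1 on each of the 4 arrays, as the scaling of the MAS5 signal to a target of 500 gives. The background correction and summary behind the values stay unknown, and low intensities, which MAS5 leaves noisy, were treated with care for that reason.

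Each value below 62.6 (log2 5.97), the median of all values in the table, was set to that floor before taking log2. The floor was not part of the design written before the data were examined. It was chosen from the distribution of the values, before any comparison between groups, and the design assumed log2 values. Arrays were not normalized further. Of 54675 probe sets, 41097 had 1 gene symbol in the platform's annotation, 1801 had several and 11777 had none here. Symbols were checked through gene identifiers, which matched 41043 probe sets and changed 0 symbols, while 54 kept the annotation's name. Probe sets with several symbols or none were not used, so genes measured only by those were not analysed here. Each of 19775 genes was represented by the probe set with the highest mean over the 4 arrays. The 14427 genes above the floor on at least 1 array were compared, and 10795 were above it on all 4. A fold against an array at the floor is a lower bound and is written as at least that fold.

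Differences were taken between log2 values as siYT minus siNC and siYT+8Br-cAMP minus siNC+8Br-cAMP (knockdown without and with 8Br-cAMP), siNC+8Br-cAMP minus siNC and siYT+8Br-cAMP minus siYT (8Br-cAMP with control and with YAP/TAZ siRNA), and the difference of differences. A gene counted as higher or lower at 2-fold (log2 difference of 1). With 1 array per group and no replicate, no test across arrays was made of these counts, and their precision is limited by the number of arrays. The counts of genes expected from independent lists are the product of the lists' sizes over the number of genes. As a yardstick of measurement error, the SD of a difference between probe sets of 1 gene was computed over 7501 probe sets of 3019 genes, all above 4 times the floor. The 23 gene lists were written from general knowledge before the data were examined. Each list's median difference was placed among 10000 random lists of the same size matched on deciles of mean level, as a description of these arrays. The 2-fold rule and the additive fit were tested on simulated data for the knockdown comparison over 14427 genes. Of genes changed by log2 1.5, 79.0% passed the size rule in both comparisons. So did 100% of those changed by 3.0 and 0 unchanged genes. The additive limma fit found 63.0% and 100%, with 0 unchanged genes. The simulated noise was equal on every array and near the SD of 0.39 between probe sets for knockdown without 8Br-cAMP. That SD was 0.54 with 8Br-cAMP. Changes were given only to genes well above the floor, and variation between cultures was not simulated. These shares are therefore no error rates for the real arrays.

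Genes were named by a rule written before the data were examined: the siRNA targets, the 10 genes highest and the 10 lowest by the smaller of the 2 knockdown differences that went the same way, the same for 8Br-cAMP, the 6 highest and 6 lowest for the difference of differences, members of the YAP/TAZ target, Hippo, steroidogenesis and granulosa lists, and up to 6 members of each other list with the largest mean difference. The ranking was restricted to the 10795 genes above the floor on all arrays, after a first look at the ranked genes, because values at the floor have no order. Where a list is said to have few genes at 2-fold in both comparisons, those genes were named too, after their values were seen, as were the list members named as counterexamples.

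Alternatives written before the data were examined were no level filter, a filter at the 75th percentile of all values (388.7), the mean over all probe sets of a gene, the exclusion of probe sets shared between transcripts by their suffix, cyclic loess between arrays, a threshold of 1.5-fold, and an additive limma fit with knockdown and 8Br-cAMP as factors and 1 residual degree of freedom (Benjamini-Hochberg level 0.05). No floor, a floor at 200 and the omission of the siYT+8Br-cAMP array were added after seeing the data. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, R 4.3.3 with limma 3.58.1, and matplotlib 3.10.9.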

Results

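Gene expression was measured in KGN cells, a human line derived from an ovarian granulosa cell tumour, on 4 microarrays that hybridise labelled RNA to short probes (Affymetrix HG-U133 Plus 2.0). Granulosa cells surround the oocyte, and they make oestrogen from androgen when cyclic AMP rises in response to gonadotropins. The design crossed 2 factors. Cells received a control siRNA at 10 nM (siNC) or siRNAs against YAP and TAZ at 5 nM each (siYT), the paired transcriptional co-activators that the Hippo pathway restrains. After 48 h the medium was replaced with or without 0.5 mM 8Br-cAMP, a cell-permeable cyclic AMP analogue, for 24 h. Each of the 4 groups (siNC, siNC+8Br-cAMP, siYT and siYT+8Br-cAMP) held 1 array, so no difference reported here has a replicate check, and differences are given as sizes without p-values, apart from the counts of an additive fit.

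The median signal intensity over 54675 probe sets was 56.9 in siNC, 62.6 in siNC+8Br-cAMP, 64.1 in siYT and 66.3 in siYT+8Br-cAMP. Between 48.7% and 51.7% of values on each array lay below the floor of 62.6, as its choice as the median of all values implies. After the filter on level, 14427 genes remained. Without replicates, the spread between probe sets of 1 gene served as a yardstick of measurement error for the sizes. This spread covers only probe sets above 4 times the floor, and it leaves out variation between cultures, which probe sets of 1 array share. Its SD on the log2 scale was 0.39 for knockdown without 8Br-cAMP and 0.37 for 8Br-cAMP with control siRNA. It was 0.54 and 0.53 for the comparisons that use the siYT+8Br-cAMP array. On that array the ratio of 3' to 5' signal was 1.35 for ACTB and 1.13 for GAPDH, against 1.07 to 1.14 and 0.89 to 0.96 on the other 3.

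The siRNA targets were lower on both knockdown arrays. The representative YAP1 probe set read 4915 in siNC and 4772 in siNC+8Br-cAMP, against 1295 in siYT and 1412 in siYT+8Br-cAMP, which is 3.80-fold and 3.38-fold lower. The other YAP1 probe sets were 10.2-fold and 11.5-fold lower for one (1804, 2008, 177 and 174 on the 4 arrays in that order) and 3.34-fold and 3.55-fold lower for the other (2024, 2544, 605 and 716). WWTR1, the gene for TAZ, read 5366 and 7048 with control siRNA and 1028 and 1154 after knockdown, which is 5.22-fold and 6.11-fold lower. Its other probe sets read 490, 1082, 175 and 180 for one and 259, 280, 119 and 73.1 for the other. On the log2 scale the representative differences were -1.92 and -1.76 for YAP1 and -2.38 and -2.61 for WWTR1, without and with 8Br-cAMP.

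The comparison of siYT with siNC asked which transcripts depend on YAP and TAZ, and it was made once without and once with 8Br-cAMP on separate arrays. The lists of known YAP/TAZ target genes and of cell cycle genes had negative medians after knockdown, while single steroidogenic, matrix and secreted-factor genes were higher. ANKRD1, a muscle ankyrin-repeat protein widely used as a YAP readout, was lower by a log2 difference of -4.32 without and -4.96 with 8Br-cAMP, the latter 31.1-fold. CYP19A1, the aromatase that converts androgens to oestrogens, was 39.2-fold higher without and 3.78-fold higher with 8Br-cAMP. A second CYP19A1 probe set, below the floor in siNC, gave at least 12.1-fold and 18.8-fold. CYP11A1, the side-chain cleavage enzyme that starts steroid synthesis, was 13.0-fold and 3.86-fold higher, the former from 81.4 in siNC, near the floor.

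**Figure D1:**
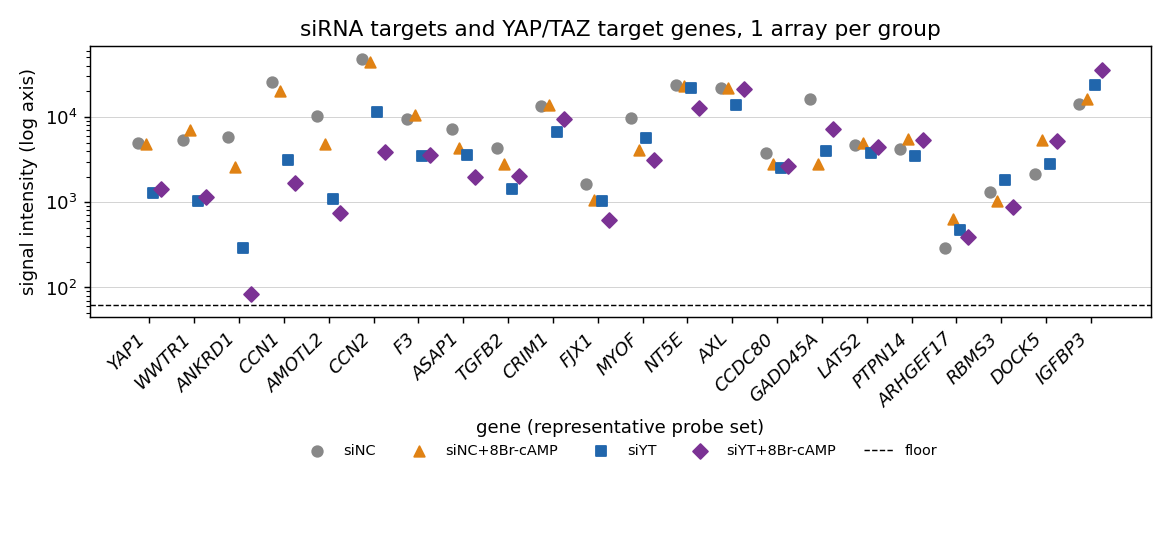
Signal intensity (log axis) of YAP1, WWTR1 and the 20 measured genes of the YAP/TAZ target list on the 4 arrays, 1 point per array, with values under the dashed floor drawn at it. YAP1 and WWTR1 were lower on both siYT arrays, and so were 15 of the 20 target genes, while IGFBP3, at the right, was higher on both.

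Of the 20 measured genes in the list of YAP/TAZ targets, 6 were at least 2-fold lower in both knockdown comparisons and 0 were at least 2-fold higher in both. The 6 were ANKRD1, AMOTL2 (a Hippo scaffold, 9.56-fold and 6.44-fold lower), CCN1 (a matricellular protein, 8.39-fold and 12.0-fold), CCN2 (4.21-fold and 11.4-fold), F3 (tissue factor, 2.71-fold and 2.92-fold) and ASAP1 (2.03-fold and 2.17-fold). Any lower value in both was seen for 15 of the 20, and 1, IGFBP3, was higher in both (log2 0.76 and 1.14). The list's median difference was -0.73 without and -0.50 with 8Br-cAMP, and 0 and 7 of 10000 random lists of the same size and matched level had a median as low. The targets AXL (-0.64 and -0.07), CRIM1 (-1.01 and -0.54), TGFB2 (-1.61 and -0.46) and LATS2 (-0.32 and -0.15) did not reach 2-fold in both. GADD45A, also on the list, went opposite ways, with -2.02 without and 1.36 with 8Br-cAMP. Among 27 genes of the Hippo pathway, 3 were higher in both, namely MAP4K4 (5.56-fold and 3.29-fold), AMOTL1 (3.49-fold and 3.02-fold) and VGLL4 (2.06-fold and 3.98-fold). The 3 that were lower in both were AMOTL2, VGLL3 (log2 -1.85 and -1.59) and WWC1 (2.21-fold and 2.41-fold). The TEAD1 transcript, for the main DNA-binding partner of YAP, differed by -0.67 and -0.90, and the list's median was -0.15 in each.

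Cell cycle transcripts were lower as a group. Of 30 genes of the G2 and M phases, 28 were at least 2-fold lower in both comparisons, and the median was 5.10-fold lower without and 3.49-fold lower with 8Br-cAMP. None of 10000 random lists had as low a median in either. CCNB1, the mitotic cyclin, was 4.38-fold and 6.40-fold lower, CDK1 5.63-fold and 3.21-fold, AURKA 6.10-fold and 3.47-fold, and KIF20A 8.39-fold and 5.43-fold. BUB1 reached 2-fold without 8Br-cAMP alone (-1.52 and -0.95), and PLK1 stayed near the floor on every array. Of 29 genes of the G1 phase and DNA replication, 14 were lower in both (medians -1.58 and -1.44), among them TYMS (6.18-fold and 5.71-fold) and UHRF1 (5.80-fold and 6.48-fold). CCND1, cyclin D1, went the other way without 8Br-cAMP (log2 1.15) and read -0.19 with it. Of 16 genes of the p53 and arrest list, 1 was lower in both, PLK2 (9.33-fold and 5.99-fold), and the cell cycle inhibitor CDKN1A differed by 0.40 and 0.86. The list's medians were 0.08 and 0.06.

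Among 22 measured steroidogenic genes, 3 were at least 2-fold higher in both knockdown comparisons and 0 were lower in both. Besides CYP19A1 and CYP11A1 this was HSD11B1, which regenerates cortisol from cortisone (9.29-fold and 8.64-fold). HSD3B2, the next enzyme after CYP11A1, was at the floor in siNC and therefore at least 2.86-fold higher without 8Br-cAMP, and 1.39-fold higher with it. STAR, the carrier that brings cholesterol into mitochondria, differed by -0.07 and -0.16. The list's medians were 0.09 and 0.11, at percentiles 78.6 and 78.0 of the random lists. Of 28 granulosa genes, 3 were higher and 3 lower in both, with medians of 0.18 and -0.29. VCAN (versican) was 3.76-fold and 2.55-fold higher and HAS2 (hyaluronan synthase) at least 3.36-fold and 2.91-fold higher, while KRT18 was 4.82-fold and 6.89-fold lower, ADAMTS1 12.6-fold and 3.60-fold lower, and PTX3 5.10-fold and 13.9-fold lower.

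The 10 genes that were highest after knockdown in both conditions were ANGPTL4, GLDN, ANTXR2, HSD11B1, LUM, SLC6A8, TMEFF2, MGP, MAF and SHC4. ANGPTL4, a secreted inhibitor of lipoprotein lipase, was higher by 4.46 and 3.73 on the log2 scale, the neural adhesion protein GLDN 14.4-fold and 10.4-fold, and the collagen-binding proteoglycan LUM 12.1-fold and 8.51-fold. ANTXR2 was 10.4-fold and 10.1-fold higher, the creatine transporter SLC6A8 8.79-fold and 7.96-fold, and MGP, an inhibitor of calcification, 6.42-fold and 7.65-fold. The 10 lowest were ANKRD1, HMOX1, CPA4, CEP55, CCN1, OXTR, ZWINT, NPPB, AMOTL2 and RRM2. HMOX1, which degrades haem, was 20.4-fold and 12.8-fold lower, the secreted carboxypeptidase CPA4 12.0-fold and 9.96-fold, the oxytocin receptor OXTR 7.17-fold and 9.88-fold, and the natriuretic peptide NPPB 8.25-fold and 6.52-fold. CEP55, ZWINT and RRM2 serve cell division or DNA synthesis, and they were 9.17-fold, 6.67-fold and 7.19-fold lower without 8Br-cAMP.

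On the matrix, hypoxia and inflammation lists, fewer genes reached 2-fold in both comparisons than on the cell cycle lists. Of 29 extracellular matrix genes, 3 were higher in both comparisons (TNC 4.12-fold and 2.08-fold, LAMA4 3.55-fold and 3.56-fold, COL5A1 2.33-fold and 2.78-fold) and 2 were lower in both (THBS1 6.20-fold and 3.51-fold, FBN2 4.18-fold and 2.44-fold). The median was 0.43 without and 0.24 with 8Br-cAMP, at percentiles 99.9 and 88.7 of the random lists. Of 23 glycolysis and hypoxia genes, NDRG1 (4.12-fold and 4.81-fold), VEGFA (2.64-fold and 3.63-fold) and PFKFB3 (3.48-fold and 6.18-fold) were higher in both and 0 were lower, with medians of 0.21 and 0.59. Of 18 inflammatory genes, 5 were lower in both, among them IL6 (5.19-fold and 14.3-fold) and CXCL2 (2.80-fold and 2.89-fold), and 1 was higher, IL11 (3.58-fold and 2.36-fold). The inflammatory medians were -0.59 and -0.11, at percentiles 0.07 and 29.9. Of 23 actin and contractile genes, ACTA2 (3.48-fold and 3.23-fold), TAGLN (3.25-fold and 4.55-fold) and CNN1 (4.29-fold and 3.51-fold) were lower in both, with medians of -0.38 and -0.36. Without probe sets shared between transcripts, the TAGLN difference without 8Br-cAMP was log2 0.39. Of 36 CREB target genes, 4 were higher in both (NR4A2, DUSP4, PPARGC1A and PTGS2, medians 0.38 and 0.17). In the TGF-beta and BMP list 2 of 21 were higher in both, BMP6 and LTBP1 (medians 0.56 and -0.01). The unfolded protein response list had 1 of 20 higher (CRELD2) and 2 lower (ASNS and PSAT1), with medians of 0.24 and 0.39. The interferon list had 1 of 28 higher in both (IFI6, medians 0.01 and -0.36), and the cholesterol synthesis list 1 of 19 lower in both (ACAT2, medians -0.24 and 0.03).

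**Figure D2:**
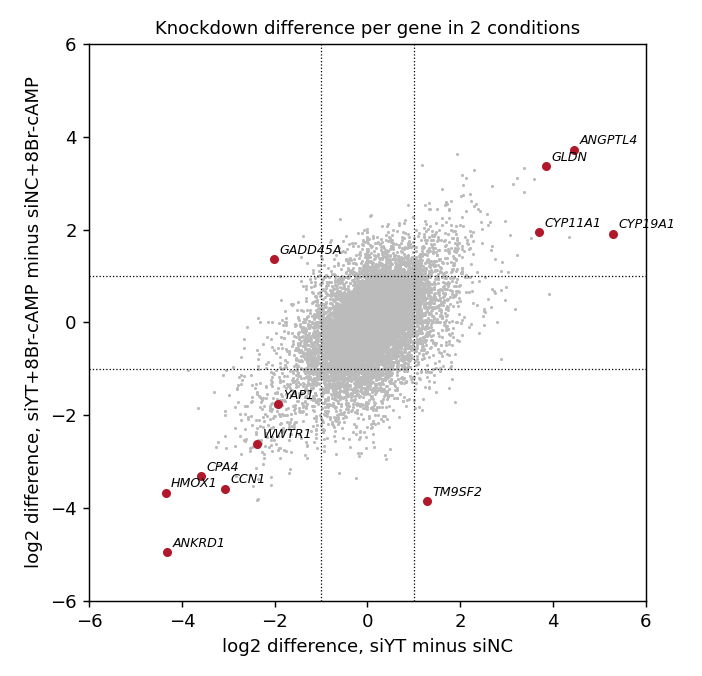
Log2 difference of each of 14427 genes after YAP/TAZ knockdown without 8Br-cAMP (horizontal axis) and with it (vertical axis), with dotted lines at 2-fold. ANKRD1, HMOX1 and CCN1 lie at the lower left and ANGPTL4 and GLDN at the upper right, while CYP19A1 lies at 5.29 and 1.92 and TM9SF2 and GADD45A have opposite signs on the axes.

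Across genes, 1053 were at least 2-fold higher and 873 lower after knockdown without 8Br-cAMP, and 973 higher and 1367 lower with it. The overlap was 343 genes higher in both and 406 lower in both, against 71.0 and 82.7 for independent lists, and 44 went opposite ways. The comparisons share no array, and their differences correlated across genes at r = 0.51 (Spearman rho 0.44), where genes are not independent replicates. An additive limma fit of both factors, which takes the difference of differences as error with 1 residual degree of freedom, called 95 genes higher and 162 lower at a Benjamini-Hochberg level of 0.05. Without the siYT+8Br-cAMP array only the 1926 genes of the comparison without 8Br-cAMP remain, of which 29 are in the G2 and M list and 9 of the lower ones in the YAP/TAZ target list.

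The comparisons with 8Br-cAMP asked how cyclic AMP alters these cells, with control siRNA and after YAP/TAZ knockdown. STAR, CYP19A1, CYP11A1 and HSD3B2, which cyclic AMP is known to induce in granulosa cells, were higher, and so were 11 of 36 CREB target genes, while the inflammatory, contractile and cell cycle lists had negative medians. STAR read 1284 in siNC and 37308 in siNC+8Br-cAMP, a 29.0-fold difference, and 1227 and 33335 after knockdown, a 27.2-fold difference. CYP19A1 was 35.7-fold and 3.44-fold higher and CYP11A1 14.4-fold and 4.28-fold higher, with control siRNA and after knockdown. The 14.4-fold starts from a CYP11A1 reading of 81.4 in siNC, near the floor. By its second probe set CYP19A1 was at least 5.70-fold and 8.82-fold higher. IL11, an interleukin-6 family cytokine, was 82.5-fold and 54.4-fold higher, and 13.3-fold and 22.1-fold by its other probe set.

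**Figure D3:**
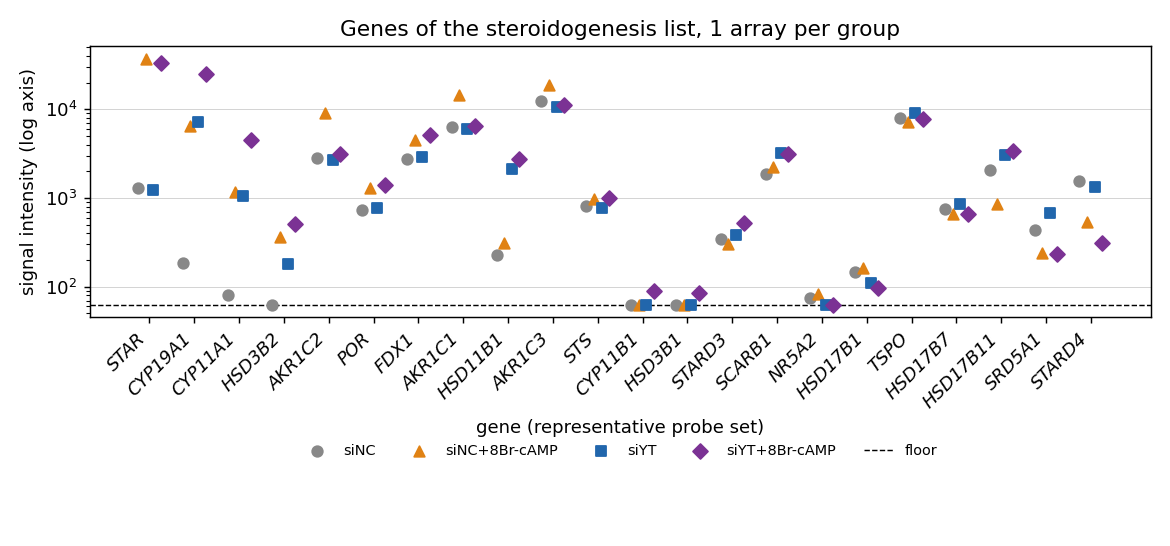
Signal intensity (log axis) of the 22 measured genes of the steroidogenesis list on the 4 arrays, 1 point per array, with values under the dashed floor drawn at it. STAR was higher on both 8Br-cAMP arrays with either siRNA, CYP19A1 and CYP11A1 were higher with 8Br-cAMP and with knockdown, and HSD11B1 with knockdown.

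Of the 22 steroidogenic genes, 4 were at least 2-fold higher with 8Br-cAMP in both comparisons (STAR, CYP19A1, CYP11A1 and HSD3B2) and 1 was lower in both, the cholesterol carrier STARD4 (2.91-fold and 4.23-fold). HSD3B2 was at least 5.81-fold higher with control siRNA, since siNC was at the floor, and 2.83-fold higher after knockdown. The electron donors FDX1 (log2 0.73 and 0.81) and POR (0.81 and 0.83) were higher by less than 2-fold. The aldo-keto reductases AKR1C1 (1.21 and 0.14) and AKR1C2 (1.69 and 0.20) were higher with control siRNA and nearly level after knockdown. Both were read by probe sets whose suffix marks them as shared between transcripts, so these genes may not have been read separately. The list's medians were 0.24 and 0.28, at percentiles 98.1 and 97.0. Of 28 granulosa genes, 4 were higher in both, namely CYP19A1, FOXL2 (the granulosa transcription factor, 2.23-fold and 2.43-fold), INHA (inhibin alpha, 4.69-fold and 3.14-fold) and HAS2 (at least 4.14-fold, and 3.58-fold). INHA read 70.5 in siNC and 66.1 in siYT, near the floor. The 3 lower in both were PTX3, RUNX2 (2.23-fold and 6.09-fold) and INHBB (2.32-fold and 2.55-fold). GATA4 (1.05 and 0.75) reached 2-fold with control siRNA alone, and the medians were 0.32 and 0.00.

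Of 36 CREB target genes, 11 were higher in both 8Br-cAMP comparisons and 2 lower in both (BTC and EGR1). The cyclic AMP phosphodiesterases PDE4D (3.72-fold and 3.52-fold) and PDE7B (10.6-fold and 4.25-fold), the kinase SIK1 (4.12-fold and 6.69-fold) and the repressor CREM (2.58-fold and 2.30-fold) were among the higher genes. When probe sets shared between transcripts were excluded, the CREM difference after knockdown was log2 -0.87. NR4A2, an orphan nuclear receptor at the floor in siNC, was at least 4.72-fold higher with control siRNA and 5.45-fold higher after knockdown. The medians were 0.33 and 0.40, and 2 and 0 of 10000 random lists had as high a median. In the TGF-beta and BMP list 3 of 21 were higher in both (BMP6, ID1 and ID3), with medians of 0.39 and 0.10.

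The inflammatory, contractile and unfolded protein response lists had negative medians with 8Br-cAMP in both comparisons. Of 18 inflammatory genes, 7 were lower in both and 2 were higher in both (IL11 and TNFAIP3), and 0 of 10000 random lists had as low a median as -1.03 and -1.05. The neutrophil chemokines CXCL8 (5.75-fold and 9.52-fold), CXCL1 (9.67-fold and 3.59-fold) and CXCL3 (6.57-fold and 5.03-fold) and the adhesion molecule VCAM1 (4.13-fold and 5.89-fold) were among the lower genes. Of 23 actin and contractile genes, 5 were lower in both (ACTA2, TAGLN, CNN1, TGFB1I1 and PDLIM7), with medians of -0.46 and -0.65, and ACTA2 was 3.34-fold and 3.09-fold lower. Of 20 genes of the unfolded protein response list, 4 were lower in both, namely DDIT3 (8.07-fold and 3.47-fold), TRIB3 (5.18-fold and 3.12-fold), ASNS (3.40-fold and 3.26-fold) and PSAT1 (2.44-fold and 7.17-fold). These 4 are also targets of the amino acid response. By any amount, 12 of the 20 were lower in both, among them XBP1 (-0.81 and -0.87) and PDIA4 (-0.08 and -0.18). Another 6 were higher in both, among them the chaperones HSPA5 (0.03 and 0.32) and HYOU1 (0.83 and 0.66). The median was -0.35 and -0.41. Of 28 interferon genes, IFIT2, IFIT3, MX1 and IRF1 were lower in both, with medians of -0.14 with control siRNA and -0.83 after knockdown.

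Cell cycle, cholesterol synthesis and p53 lists had negative medians with 8Br-cAMP in both comparisons. The G2 and M list had medians of -0.75 and -0.49, with 3 of 30 lower in both (HMMR, NUSAP1 and ANLN), and the G1 and replication list -0.76 and -0.66, with 5 of 29 lower in both (TYMS, GINS1, GINS2, PRIM1 and UHRF1). The cholesterol synthesis list had a median of -0.73 with control siRNA, which 0 of 10000 random lists reached, and -0.12 after knockdown. LSS, ACAT2 and STARD4 were lower in both, and LSS (lanosterol synthase) was 5.66-fold and 4.44-fold lower. The p53 and arrest list had medians of -0.60 and -0.40, with 1 of 16 higher in both (GDF15). The GDF15 difference after knockdown was -0.16 when probe sets shared between transcripts were excluded. The YAP/TAZ target list had medians of -0.24 and -0.11, and ANKRD1 alone was lower in both, 2.27-fold and 3.53-fold. In the Hippo list 3 of 27 were lower in both (FAT4, FRMD6 and VGLL2), with medians of -0.04 and -0.15. The extracellular matrix list had 2 of 29 lower in both (TIMP3 and TNC, medians -0.03 and -0.03), and the glycolysis and hypoxia list 0 of 23 either way (medians 0.03 and 0.02).

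The 10 genes that were highest with 8Br-cAMP in both comparisons were IL11, STAR, DIO2, HLA-DRA, DNAJC12, IGFBP4, PDK4, HLA-DMB, WDR91 and ALPL. DIO2, which activates thyroid hormone, was 14.8-fold and 62.4-fold higher. Its other probe sets above the floor on all arrays gave 2.12-fold and 8.12-fold for one and 10.2-fold and 25.1-fold for the other. PDK4, an inhibitor of pyruvate dehydrogenase, was 9.54-fold and 18.4-fold higher, and IGFBP4 11.8-fold and 10.2-fold. The co-chaperone DNAJC12 was 14.9-fold and 10.7-fold higher and alkaline phosphatase ALPL 8.35-fold and 7.34-fold. The 10 lowest were SLC25A24, EVI2A, SCG5, MYL12A, PTX3, CXCL8, CXCL3, CLDN1, LSS and IFIT2. The mitochondrial carrier SLC25A24 was 8.11-fold and 12.3-fold lower, the myosin light chain MYL12A 6.97-fold and 9.97-fold, the pentraxin PTX3 6.43-fold and 17.5-fold, and the tight junction gene CLDN1 4.86-fold and 6.65-fold. Of the 40 genes ranked for knockdown or 8Br-cAMP, 15 had other probe sets above the floor on all arrays. All 17 of these went the same way as the representative and 15 reached 2-fold in both comparisons, the exceptions being those of LSS (2.16-fold and 1.96-fold) and IFIT2 (1.59-fold and 1.49-fold), and 10 gave smaller values in both.

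Across genes, 626 were at least 2-fold higher and 753 lower with control siRNA, and 722 higher and 1425 lower after knockdown. In both comparisons 210 were higher and 300 lower, against 31.3 and 74.4 for independent lists, and 33 went opposite ways. The differences correlated across genes at r = 0.45 (rho 0.38), with no array shared. The additive limma fit called 16 genes higher and 4 lower at a Benjamini-Hochberg level of 0.05, 20 in place of 510. Without the siYT+8Br-cAMP array only the 1379 genes seen with control siRNA remain.

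Whether knockdown alters the response to 8Br-cAMP was asked by the difference of differences, the 8Br-cAMP difference after knockdown minus that with control siRNA. CYP19A1 had one of the lowest values (-3.38): it read 184, 6558, 7213 and 24784 in siNC, siNC+8Br-cAMP, siYT and siYT+8Br-cAMP. The intensity under both treatments was the highest of the 4, 135-fold above siNC, yet below the 257184 that the product of the single folds gives and above the 13587 that the sum of the single increases gives. The second CYP19A1 probe set read below the floor in siNC and 357, 761 and 6706 on the others, so that its 8Br-cAMP difference was at least 5.70-fold with control siRNA and 8.82-fold after knockdown. CYP11A1 read 81.4, 1171, 1056 and 4518 (-1.75), again between the sum (2145) and the product (15197). STAR differed by -0.10.

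Of the 28 granulosa genes, 9 had a difference of differences at least 2-fold lower and 3 at least 2-fold higher, with a median of -0.40 at percentile 0.31 of random lists. IGFBP5, a binding protein for insulin-like growth factors, was 6.99-fold higher with 8Br-cAMP under control siRNA and 1.41-fold lower after knockdown (-3.30). The G2 and M list had a median of 0.41 and the cholesterol synthesis list 0.35 (percentiles 99.9 and 99.3), that is, their 8Br-cAMP differences were less negative after knockdown. Besides CYP19A1 and IGFBP5, the 6 lowest genes were TM9SF2 (-5.15), JUP (-3.67), RBL2 (-3.24) and CLIP1 (-3.23). The 6 highest were GADD45A (3.38), ARMC7 (3.26), PIGW (2.89), RAB23 (2.84), TM7SF2 (2.55) and SYBU (2.53). Other probe sets gave other values: -1.97, -1.32, 0.00, 0.83 and 0.97 for IGFBP5 (from probe sets that read at most 262 on any array), -0.47 for RBL2, 0.27, 0.13 and 0.05 for CLIP1, 0.83 for ARMC7, and 0.09 and -1.40 for RAB23. TM9SF2, JUP, GADD45A, PIGW, TM7SF2 and SYBU had 1 probe set each. Among them, JUP (75.6, 115, 558 and 66.9 on the 4 arrays), PIGW (400, 78.9, 108 and 157) and TM7SF2 (290, 89.8, 169 and 308) had low readings. These lay below 4 times the floor, where the SD between probe sets was not measured. The plot of list medians gives the 2-array comparisons side by side.

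**Figure D4:**
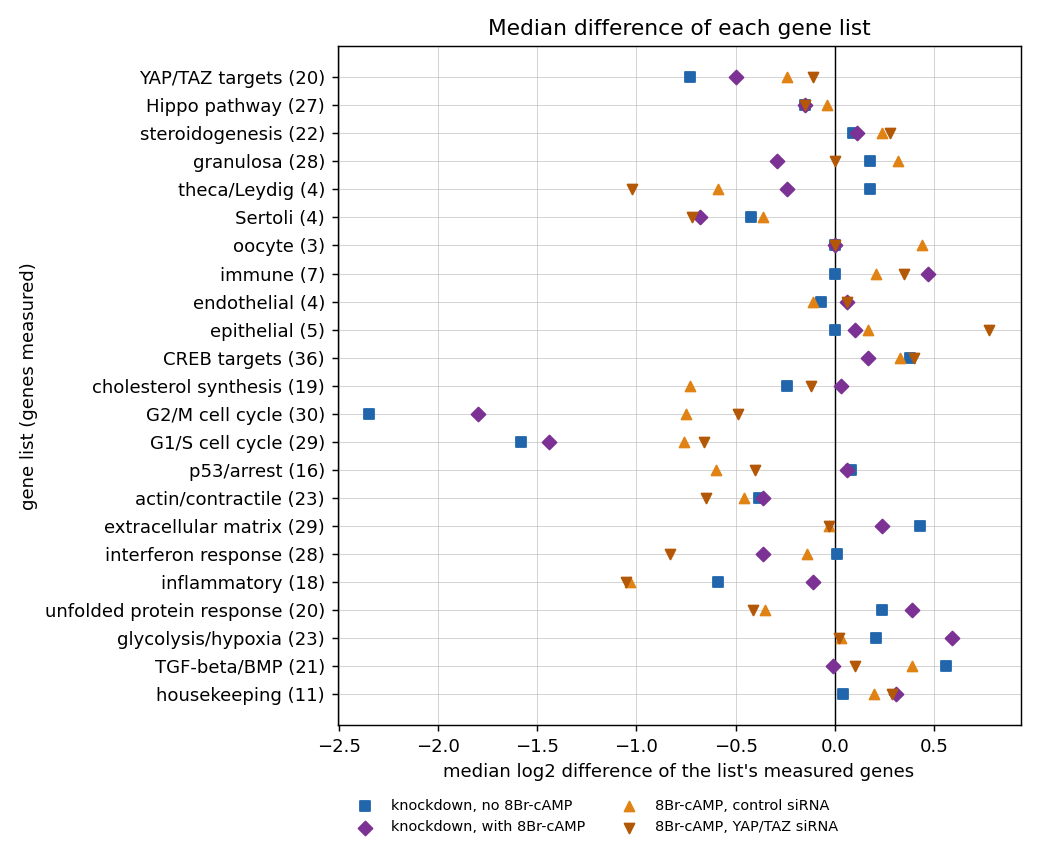
Median log2 difference of each of the 23 gene lists (number of measured genes in brackets) in the knockdown comparisons without and with 8Br-cAMP and the 8Br-cAMP comparisons with control and YAP/TAZ siRNA. The G2 and M list lies farthest to the left, at -2.35 and -1.80 for knockdown, and the inflammatory list at -1.03 and -1.05 for 8Br-cAMP.

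Over all genes, 778 had a difference of differences at least 2-fold higher and 1379 lower. The 4 arrays leave 0 residual degrees of freedom, so array noise and interaction cannot be separated by a test, and the SD of this value between probe sets of 1 gene was 0.60. Lower values made up 63.9% of the total as deposited and 53.2% after cyclic loess scaling.

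Few markers of other cell types reached 2-fold in the same direction in both comparisons of a factor. Some of these markers read high, such as CLDN11 (25029 in siNC) and ACTA2 (11044 in siNC). In the immune list 1 of 7 measured markers, CD74, was at least 2-fold higher with 8Br-cAMP in both comparisons (medians 0.21 and 0.35), and 0 were so after knockdown (0.00 and 0.47). In the theca and Leydig list ACTA2, also a contractile gene, was lower in all 4 comparisons (list medians 0.18 and -0.24 for knockdown, -0.59 and -1.02 for 8Br-cAMP), and PDGFRA read 553, 548, 3493 and 687. In the Sertoli list CLDN11 was 4.32-fold and 4.21-fold lower after knockdown and 2.26-fold and 2.20-fold lower with 8Br-cAMP (list medians -0.42, -0.68, -0.36 and -0.72). The oocyte (3 measured), endothelial (4) and epithelial (5) lists had 0 genes that reached 2-fold in the same direction in both comparisons of either factor. Their medians for knockdown and 8Br-cAMP were 0.00, 0.00, 0.44 and 0.00 for oocyte, -0.07, 0.06, -0.11 and 0.06 for endothelial, and 0.00, 0.10, 0.17 and 0.78 for epithelial markers. Of 11 housekeeping genes 0 reached 2-fold in both comparisons of a factor, with medians of 0.04, 0.31, 0.20 and 0.29.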

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

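The tests in this part of probe set spread were chosen after the result was seen, and the one of cyclic loess scaling before it.

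Among 446 named genes and list members, GADD45A, ARMC7, RAB23, TM9SF2 and CLIP1 had 2-fold differences of opposite sign in the comparisons of one factor, and these differences between conditions were not tested. All of them had been named for the largest differences of differences, a choice that favours opposite signs. Over all 14427 genes, 44 had opposite 2-fold differences for knockdown and 33 for 8Br-cAMP. GADD45A, a growth arrest and DNA damage gene that is also on the YAP/TAZ target list, was lower after knockdown without 8Br-cAMP (log2 -2.02). With 8Br-cAMP it was higher (1.36), a difference of differences of 3.38. ARMC7 did the same for knockdown (-1.39 and 1.87) and for 8Br-cAMP (-1.32 and 1.94), with a difference of differences of 3.26. Its other probe set did not show this, with -0.82 and 0.00 for knockdown and -0.61 and 0.22 for 8Br-cAMP. RAB23 was lower with 8Br-cAMP under control siRNA (-1.82) and higher after knockdown (1.01), a difference of 2.84, where its other probe sets gave 0.09 and -1.40. TM9SF2 was higher after knockdown without 8Br-cAMP (1.29) and lower with it (-3.86), a difference of -5.15. CLIP1 was higher with 8Br-cAMP under control siRNA (1.12) and lower after knockdown (-2.11), a difference of -3.23 that its other probe sets did not show, and the mean over all its probe sets gave -0.03 in place of the 1.12. In each case the siYT+8Br-cAMP array enters 1 of the 2 differences.

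The hybridisation control probe sets, which read RNA added to every hybridisation and enter no comparison, were higher on the siYT+8Br-cAMP array than on the siNC array by a median of 0.49 (1.41-fold, 17 of 18 probe sets higher). Against siNC, the medians were 0.08 for siYT and 0.13 for siNC+8Br-cAMP. In the comparisons with the siYT+8Br-cAMP array more genes were lower than higher (66.4% lower for 8Br-cAMP after knockdown and 58.4% for knockdown with 8Br-cAMP). The SD between probe sets of 1 gene was 1.40 times as large in comparisons that use that array. A wider spread adds genes both ways. For 8Br-cAMP the higher and the lower genes were both more in the comparison with that array (722 against 626 and 1425 against 753). For knockdown the lower ones were (1367 against 873) and the higher ones were not (973 against 1053), except after cyclic loess (1026 against 907). Whether less even measurement contributes thus stays open, and a wider spread alone predicts no direction. Whether intensity-dependent scaling contributes stays open: after cyclic loess the lower share for 8Br-cAMP after knockdown was 57.3%, between the bounds set for either answer. A true response to the combined treatment is named by the design and was not tested, because that group has 1 array.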

How the results depend on the processing

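No floor, the floor at 200 and the omission of 1 array were chosen after seeing the data, while the other alternatives were planned. No target and none of the 92 differences by which genes were ranked changed direction under the alternatives run for them (averaging, exclusion of shared probe sets, cyclic loess, no floor and the floor at 200). Over the same 5 alternatives and every 2-fold difference of the 446 named genes and list members, 20 of 3390 comparisons with the reported value had the opposite sign, 12 of them without shared probe sets and 0 after cyclic loess. Among values given in the text these were CLIP1 for 8Br-cAMP with control siRNA (1.12, and -0.03 after averaging) and, without shared probe sets, CREM for 8Br-cAMP after knockdown (2.30-fold higher, and log2 -0.87) and TAGLN for knockdown without 8Br-cAMP (-1.70, and 0.39). The reported higher value of GDF15 for 8Br-cAMP after knockdown (2.37, and -0.16) did so too. No paired analysis was possible because each group had 1 array without a replicate number, and of the alternatives the additive limma fit alone has a test. The floor of 62.6 is the median of all values, so the 48.7% to 51.7% of values below it on each array follow from that choice. They do not measure signal over background.

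Averaging all probe sets of a gene, which includes probe sets at the floor, gave 1199 and 1320 genes for knockdown without and with 8Br-cAMP, 466 in both, 801 and 1164 for 8Br-cAMP with control and YAP/TAZ siRNA, 283 in both, and 1153 for the difference of differences. In the same order, a threshold of 1.5-fold gave 4726, 5457, 2223, 3860, 5245, 1660 and 5252, and no floor gave 3107, 3891, 1171, 2679, 3692, 954 and 3893. A floor at 200 gave 1454 for knockdown with 8Br-cAMP, 890, 1378 and 337 for 8Br-cAMP, and 1249 for the difference of differences. A filter at the 75th percentile gave 1231 for the last, with fewer genes compared. The additive limma fit called 257 genes for knockdown in both conditions (749 by size) and 20 for 8Br-cAMP (510 by size), with 2859 and 2254 at an unadjusted p under 0.05 and smallest adjusted p-values of 0.036 and 0.013. Leaving out the siYT+8Br-cAMP array leaves single comparisons in place of the overlaps, 1926 for knockdown and 1379 for 8Br-cAMP. The other 29 alternative counts, those after cyclic loess among them, stayed within 1.5 times. No level filter changes no count by construction. Averaging moved the targets to -2.34 and -2.37 for YAP1 and -1.66 for WWTR1 without 8Br-cAMP, and the other 17 target values moved by less than the SD between probe sets. Of the named genes' values 384 moved by less than that SD and 65 by more.

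List medians, averaged over the comparisons of a factor, moved by less than the spread of random lists in 214 cases and by more in 60; values follow with the reported median in brackets. Small lists near the floor moved most, and the cause was not tested. No level filter adds genes at the floor and gave, for knockdown, Hippo -0.02 (-0.15), theca/Leydig 0.00 (0.37), Sertoli 0.00 (-0.37), immune 0.09 (0.22) and endothelial 0.00 (-0.24). For 8Br-cAMP it gave YAP/TAZ targets -0.15 (-0.28), steroidogenesis 0.13 (0.29), theca/Leydig -0.04 (-0.80), Sertoli 0.00 (-0.41), oocyte 0.00 (0.22), endothelial 0.00 (-0.24) and epithelial 0.02 (0.62). Averaging probe sets gave, for knockdown, G2/M -1.78 (-2.12), G1/S -1.14 (-1.29), inflammatory -0.09 (-0.36) and unfolded protein response 0.07 (0.25). For 8Br-cAMP it gave steroidogenesis 0.18 (0.29), theca/Leydig -0.25 (-0.80), epithelial 0.12 (0.62), CREB targets 0.29 (0.40), unfolded protein response -0.26 (-0.43) and glycolysis 0.06 (0.25). Excluding shared probe sets gave, for knockdown, Sertoli -0.82 (-0.37), endothelial -0.53 (-0.24), G1/S -1.43 (-1.29), p53 0.27 (-0.06), actin -0.19 (-0.45), TGF-beta 0.05 (0.26) and housekeeping -0.05 (0.17). For 8Br-cAMP it gave YAP/TAZ targets -0.70 (-0.28), endothelial -0.53 (-0.24), epithelial 0.05 (0.62), CREB targets 0.30 (0.40), G2/M -0.74 (-0.62), inflammatory -0.54 (-0.88), TGF-beta 0.15 (0.35) and housekeeping -0.16 (0.24). Cyclic loess gave epithelial -0.70 (-0.12) for knockdown, and extracellular matrix -0.19 (-0.03) and glycolysis 0.08 (0.25) for 8Br-cAMP. No floor gave, for knockdown, granulosa -0.23 (-0.10), oocyte 0.17 (0.05), endothelial -0.60 (-0.24) and epithelial -0.69 (-0.12). For 8Br-cAMP it gave oocyte 0.85 (0.22), immune 0.41 (0.23), endothelial -0.71 (-0.24), epithelial 0.89 (0.62), CREB targets 0.54 (0.40), inflammatory -1.19 (-0.88) and glycolysis 0.06 (0.25). The floor at 200 gave, for knockdown, theca/Leydig -0.10 (0.37), immune 0.99 (0.22), endothelial 0.12 (-0.24), epithelial -0.46 (-0.12), G2/M -1.98 (-2.12) and G1/S -1.05 (-1.29). For 8Br-cAMP it gave immune 1.91 (0.23), epithelial 0.35 (0.62) and glycolysis 0.06 (0.25), and the oocyte list had no genes left.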

Other observations

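The tests here of bright genes, of leukocyte markers, of the 4 class II genes and of probe set pairs as low as CYP19A1 were chosen after the results were seen, and the one of brighter probe set pairs before.

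The MHC class II genes, which present antigen and are usually expressed by immune cells, were in part higher with 8Br-cAMP. This list was drawn up after HLA-DRA and HLA-DMB had appeared among the 10 highest genes, so that its values describe the pattern and do not test it. Of 11 measured genes on the list 7 were at least 2-fold higher in both 8Br-cAMP comparisons and 0 lower. The 7 include CD74 and CIITA, which are described below and are not class II chains. The other 4 were HLA-DPA1 (log2 1.90 with control siRNA and 0.69 after knockdown, while its other probe sets passed in both, with 2.88 and 3.39 for one and 2.75 and 1.80 for the other after values below the floor were set to it), HLA-DOA (0.00 and 1.19), HLA-DQA1 (0.42 and 0.00) and HLA-DQB1 (0.14 and -0.77). HLA-DRA was 13.3-fold higher with control siRNA and 16.1-fold after knockdown, HLA-DPB1 7.28-fold and 9.31-fold, HLA-DMA 4.73-fold and 4.63-fold, HLA-DMB 8.81-fold and 11.3-fold, and the invariant chain CD74 3.72-fold and 3.78-fold. HLA-DRA read 67.5 in siNC, near the floor. The other CD74 probe sets gave log2 0.22 and 1.99 for one and 0.00 and -0.34 for the other. The representative probe set of CIITA, the transactivator of these genes, was at the floor without 8Br-cAMP on both arrays and read 220 in siNC+8Br-cAMP and 161 in siYT+8Br-cAMP, so that it was at least 3.51-fold and 2.58-fold higher. The other CIITA probe sets did not reach 2-fold: in siNC, siNC+8Br-cAMP, siYT and siYT+8Br-cAMP one read 62.3, 40.4, 67.6 and 34.7 and the other 45.1, 38.0, 20.3 and 88.7.

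Of the activin and follistatin genes, INHBA and FST were at least 2-fold lower after knockdown without 8Br-cAMP, while with 8Br-cAMP INHBA reached 2-fold higher after knockdown alone (log2 0.86 with control siRNA and 2.72 after knockdown) and FST 2-fold lower with control siRNA alone (-1.66 and -0.44). INHBA, the activin A subunit, read 17150 in siNC, 31170 in siNC+8Br-cAMP, 5097 in siYT and 33512 in siYT+8Br-cAMP. It was thus 3.36-fold lower after knockdown without 8Br-cAMP and 1.08-fold higher with it, and its other probe sets read 6482, 9838, 1475 and 25910 for one and 104, 62.1, 50.8 and 274 for the other, near the floor. FST, the activin antagonist, was 4.59-fold lower after knockdown without and 1.97-fold lower with 8Br-cAMP (2.05-fold and 2.20-fold in the latter by its other probe sets) and 3.17-fold lower with 8Br-cAMP under control siRNA, and it read 19442, 6136, 4236 and 3122. INHBB, the activin B subunit, differed by 0.999 and 0.859 for knockdown, short of 2-fold, and was lower with 8Br-cAMP in both (-1.21 and -1.35). These genes were chosen after their values were seen, and the siYT+8Br-cAMP values rest on 1 array.

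The source of the class II pattern stays open. Leukocytes are an unlikely source by design, because the cultures were of a cell line. Of the 6 other leukocyte markers measured, 0 were at least 2-fold higher in both 8Br-cAMP comparisons. Their highest reading on any array was 170.1. Each of the 6 was at the floor on at least 1 array, and markers that low do not decide it by themselves. For one transcript read by probe sets of its paralogs, 4 of 4 genes from different families or chains (HLA-DRA, HLA-DMA, HLA-DMB and CD74) were higher in both, but HLA-DRA and HLA-DMB prompted the list, so that this count does not decide it either. Induction of CIITA by cyclic AMP in KGN cells was not tested, and 1 of its 3 probe sets was at least 2-fold higher in both comparisons.

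CYP19A1 had a smaller fold with 8Br-cAMP after knockdown (3.44) than with control siRNA (35.7). Saturation of bright signals and error of single probe sets both stay open. The 16 other genes that were higher with 8Br-cAMP and as bright had a median difference of differences of -0.13 (SD 0.70), but only 5 of them were at least 2-fold brighter in siYT+8Br-cAMP than in siNC+8Br-cAMP, as CYP19A1 was, and the 257184 that the product of its single folds gives lies above the highest intensity on any array (147293). For error of single probe sets, of 6605 pairs of probe sets of 1 gene 0.212% differed by as much as CYP19A1's -3.38, but these all read above 250 on every array and CYP19A1 read 184 in siNC. Of 1265 pairs whose lowest reading was above the floor and no higher than 184, 8 did (0.63%, 95% interval 0.27% to 1.24%). This interval does not keep clear of 1%, the bound for excluding such error. For these pairs the bound was set after the results were seen. The interval also takes the pairs as independent, although they come from 824 genes. The second CYP19A1 probe set does not decide it, because its siNC value lay below the floor and its fold with control siRNA is only a bound (at least 5.70, against 8.82 after knockdown), and for knockdown with 8Br-cAMP it gave 18.8-fold where the representative gave 3.78-fold. Whether knockdown and cyclic AMP act on CYP19A1 through a shared limiting step was not tested, and on the linear scale the combined value exceeded the sum of the single increases.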
